A study of Mus musculus with 11 samples.

How the data were processed

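RNA abundance was measured in 11 mouse cell samples on Affymetrix expression arrays, 1 array per sample. The groups were neural stem cells (NSC, 2 arrays), induced pluripotent stem cells made from such NSC with 2 factors, Oct4 and Klf4 (2F iPS cells, 3 arrays), iPS cells made with 4 factors, which added Sox2 and c-Myc to the former pair (4F iPS cells, 3 arrays), and embryonic stem cells (ESC, 3 arrays). Per the labels, 1 microgram of total RNA was labelled with biotin in a one-cycle protocol for each array. The deposited values are log2 expression summaries per probe set that the authors made with RMA, per the submitters' processing notes. The software version and the probe set annotation behind them were not given in the sources used here. All values lay between 2.14 and 14.6, and the array medians lay between 5.55 and 5.61. The number of arrays limits the precision. The design text gives 8 hybridizations but lists 11, and all 11 arrays were used.

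Of 45101 probe sets, 64 were array controls and the other 45037 were tested. The platform table assigned 34945 probe sets to 1 gene and 932 to several genes, and 9160 are not named here. Entrez identifiers of 34741 probe sets matched the RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols and which served only for names and for the order of genes along chromosomes. The named probe sets covered 18193 genes, of which 9010 had more than 1 probe set.

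All 11 arrays entered 1 linear model of group means in limma 3.58.1 under R 4.3.3, with moderated statistics from eBayes (residual degrees of freedom 7, prior degrees of freedom 5.37). The 6 comparisons were 2F iPS cells, 4F iPS cells and ESC each against NSC, 2F iPS cells and 4F iPS cells each against ESC, and 2F against 4F iPS cells. A probe set was called when its Benjamini-Hochberg adjusted p, taken within the comparison and two-sided, was under 0.05 and its change was at least 2-fold. The last comparison is also the test of whether the changes in 2F and 4F iPS cells differed. Differences are given as log2 values with standard errors (SE) from the model, and group levels as means of log2 signal with standard deviations (SD). No batch, date or pairing is given in the labels, so no such term was fitted.

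The comparisons, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Each gene is represented by the probe set with the highest mean over the 11 arrays among those assigned to that gene alone. For 2F iPS cells against NSC, against ESC and against 4F iPS cells, the 10 genes furthest up and the 10 furthest down are named. They had to be called, to have groups that did not overlap and to have a higher group mean above the median of all values, 5.58. For the other comparisons, 3 genes in each direction are named by the same rule. Every reprogramming factor, factor relative, sex-linked gene and imprinted gene was open to naming, as were up to 4 members with the largest differences in each other list. Gene models without a symbol were skipped.

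A total of 29 lists with 445 genes were fixed, and 419 of the genes were measured. The lists held reprogramming factors, relatives of the factors, the pluripotency network, neural stem cells and radial glia, neurons, oligodendrocytes, microglia, endothelium, feeder fibroblasts, primitive endoderm, trophectoderm, primitive streak and primed epiblast, two-cell-like state, methylation-sensitive germline genes, paternally and maternally expressed imprinted genes, sex-linked genes, ribosome biogenesis, S and G2/M cell cycle, G1 cyclins and CDK inhibitors, epithelial genes, mesenchymal genes, DNA methylation and Polycomb, glycolysis, interferon and antigen presentation, p53 targets, LIF and BMP targets, immediate early and stress genes, and housekeeping genes. Each list was tested against all other genes with camera, on 1 probe set per gene and with a preset inter-gene correlation of 0.01, in each of 6 comparisons. The 174 p-values were adjusted together. As an alternative the correlation was estimated from the data. Members were counted as called over all probe sets and again with p-values adjusted over the list alone. The other listed genes had no probe set assigned to that gene alone in the tables used here.

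Overlaps between comparisons that share a control group were set beside the overlap of independent lists and beside 20 simulated data sets. In these, all arrays, those of the shared control included, differed by independent noise alone. Pearson correlations between whole arrays were compared between 2F and 4F iPS cells with an exact permutation test over 20 splits. The 3′ minus 5′ difference of the beta-actin and Gapdh control probe sets was taken as a measure of RNA integrity. Expressed genes, 11627 in number, were placed in order along the chromosomes and their differences were summarised per chromosome and per block of 25 neighbouring genes.

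The counts of called probe sets were recomputed with no fold minimum, with an adjusted p under 0.01, with dim probe sets left out (those not above the median of all values on at least 2 arrays), with quantile normalization repeated, with array medians subtracted, with a replicate block, with array weights, with a trended and robust prior, without probe sets prone to cross-hybridisation, with 1 representative or the median of the probe sets of each gene, and without each array in turn. Counts of single comparisons were also recomputed with only the arrays of the 2 groups compared. Named genes had the same alternatives as these, except the changed thresholds and the representative probe set, which already stands for each gene. The gene lists were recomputed with dim probe sets left out, both normalizations, a replicate block, the median of probe sets and without each array in turn, besides the estimated correlation. The array correlation had dim probe sets left out, quantile normalization repeated and each array left out, and was also taken as Spearman's. Leaving out genes of the shifted chromosomes, or genes of the feeder list, was chosen after the data had been seen. The chromosomes left out were 6, 13 and 14, in every comparison, whether or not the cells compared showed the shift. The procedure was tested on simulated data with known changes placed in the arrays. Of the 4-fold changes 100% were called. Of the 2-fold changes, 92.5% in 2F iPS cells against NSC, 94.0% against ESC and 97.0% against 4F iPS cells passed the adjusted p, and 58.2%, 38.8% and 49.3% also met the fold minimum. Of 45037 probe sets, 0, 2 and 3 unchanged ones were called. A list moved by 0.5 log2 was recovered, and 1 other list sharing no member with it was called.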

Results

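Genome-wide RNA levels were measured in 4 kinds of mouse cells. The NSC (n = 2) came from the brain of mice at postnatal day 5 that carried an Oct4 reporter and had a mixed background, OG2/Rosa26 crossed with ICR. The 2F iPS cells (n = 3) and 4F iPS cells (n = 3) were made from NSC with retroviruses, picked as reporter-positive colonies and grown on mouse fibroblast feeders in ESC medium. The ESC (n = 3) had the OG2/Rosa26 background and were grown on irradiated fibroblast feeders with 1000 U/ml LIF, so cell type and background differ together wherever ESC are compared. Replicate arrays correlated at a mean r across probe sets of 0.990 in 4F iPS cells, 0.994 in ESC, 0.995 in NSC and 0.996 in 2F iPS cells. The labels do not state whether replicates are separate cultures or colonies, so each p measures the spread between these samples, which may be partly technical. The 3′ minus 5′ difference of the beta-actin control was 0.55 ± 0.08 (SD) in 4F iPS cells, 0.27 ± 0.12 in ESC, 0.22 ± 0.04 in 2F iPS cells and 0.21 ± 0.02 in NSC. That of the Gapdh control was −0.04 ± 0.03, −0.07 ± 0.02, −0.09 ± 0.02 and −0.21 ± 0.02 in the same order, and so set NSC apart rather than 4F iPS cells. A group level under the median of all values, 5.58, may be background signal, and a difference from such a level is then a lower bound on the change in RNA, or no measure of its size where both groups lie under the median.

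The comparison of 2F iPS cells with NSC asks which genes separate the reprogrammed cells from the cells they were made from. Pluripotency genes rose and neural stem cell genes fell. Of 34 measured pluripotency genes, 33 rose and none fell, with a median log2 difference of 5.75. Tdgf1, a co-receptor for Nodal, rose by 9.38 ± 0.14 (log2 difference ± SE, n = 3 and 2), Pou5f1, which encodes Oct4, by 8.92 ± 0.15, Zfp42 by 8.84 ± 0.19, and Nanog by 6.97 ± 0.20. Of 37 genes of neural stem cells and radial glia, 27 fell and none rose, with a median of −3.59. They included Fabp7, a fatty acid binding protein of radial glia (−10.17 ± 0.15), the receptor phosphatase gene Ptprz1 (−7.72 ± 0.15) and Gpm6a (−7.05 ± 0.17). Both lists passed the test against other genes (adjusted p = 1.58e-23 and 1.14e-17), also with adjusted p = 0.000424 and 0.0127 with an estimated correlation. In all, 8909 probe sets were called, 3815 higher and 5094 lower, or 19.8% of those tested. They stood for 4384 genes, 2141 higher and 2243 lower. The Gapdh 3′ minus 5′ difference was −0.21 in NSC and −0.09 in 2F iPS cells.

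Among the genes furthest up were also Rps4l (8.72 ± 0.16), the cell adhesion gene Cdh1 (8.69 ± 0.16), Dppa2 (8.60 ± 0.14), L1td1 (8.54 ± 0.13), Dppa5a (8.51 ± 0.11) and the zinc finger genes Zfp982 (8.21 ± 0.20) and Zfp979 (7.94 ± 0.24). Among those furthest down were Gpm6b (−7.89 ± 0.10), the glutamate receptor gene Grm5 (−7.69 ± 0.13), the integrin gene Itgb8 (−7.52 ± 0.19), the neuronal microtubule gene Map2 (−7.46 ± 0.21), Spon1 (−7.12 ± 0.17), the GABA receptor gene Gabrg1 (−6.84 ± 0.23) and Mlc1 (−6.82 ± 0.14).

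The genes of the 4 factors did not all move together. Pou5f1 was at 3.92 ± 0.04 (SD) in NSC and at 12.84 ± 0.09 in 2F iPS cells, and Klf4 rose by 4.21 ± 0.22. Sox2 stood at 12.06 ± 0.23 in NSC and 12.05 ± 0.11 in 2F iPS cells, a difference of −0.01 ± 0.16 (adjusted p = 0.985). Myc differed by −0.82 ± 0.25 (adjusted p = 0.0174), which is under 2-fold. Signal from the retroviral copies was not separated from that of the cells' own genes. The list test gave adjusted p = 0.216. Of 8 relatives of the factors, 5 rose, among them Mycn (7.68 ± 0.21), Klf2 (5.88 ± 0.29) and Klf5 (5.18 ± 0.31), and Sox1 (−3.20 ± 0.17) and Sox3 (−3.81 ± 0.17) fell (adjusted p = 0.0559). The list of relatives was called with array medians subtracted (adjusted p = 0.0481) and without NSC replicate 2 (0.0448), 2F replicate 1 (0.0483) or 2F replicate 2 (0.0489), over a range of 0.0448 to 0.444.

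**Figure D1:**
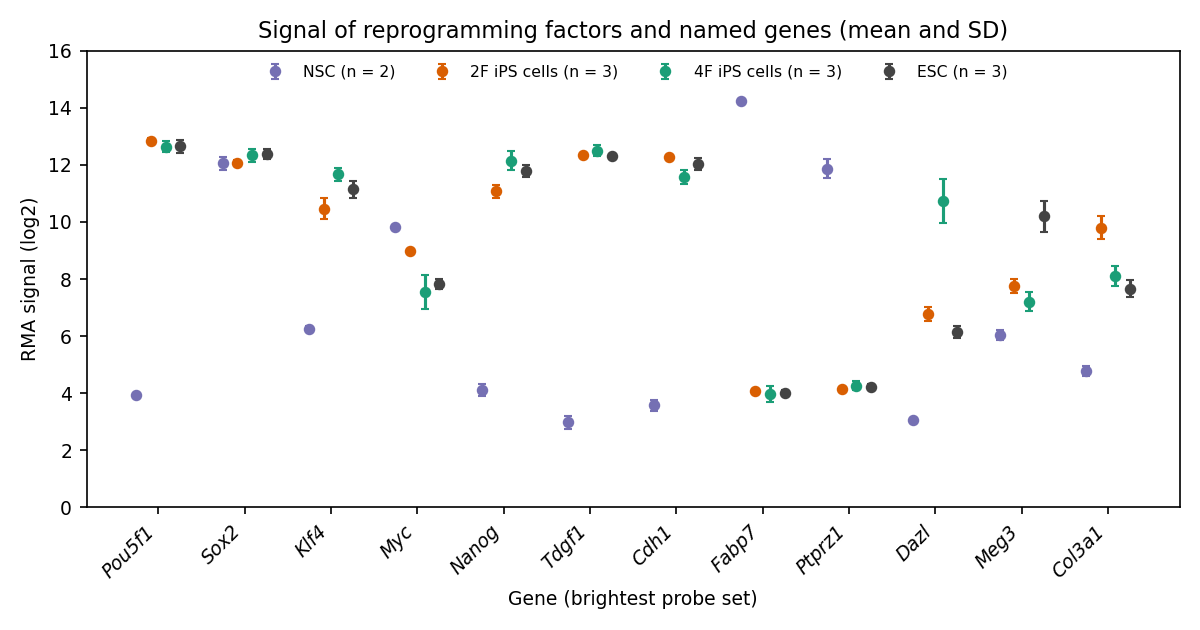
RMA log2 signal (y axis, log2 units) of 12 genes (x axis) in NSC (n = 2), 2F iPS cells, 4F iPS cells and ESC (n = 3 each), where points are means and bars SD, hidden where smaller than the point. Pou5f1 lies at 3.92 in NSC and at 12.84 in 2F iPS cells, whereas Sox2 lies at 12.06 and 12.05.

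Several other groups were higher in 2F iPS cells than in NSC. Of 16 epithelial genes, 14 rose (median 3.83), such as Epcam (6.32 ± 0.18) and the splicing factor gene Esrp1 (6.07 ± 0.21). Of 19 DNA methylation and Polycomb genes, 13 rose (median 2.06), such as the DNA methyltransferase genes Dnmt3b (6.72 ± 0.40) and Dnmt3l (7.43 ± 0.22). Of 17 germline genes, 12 rose (median 2.09), such as Tex19.1 (7.41 ± 0.29) and Mael (5.16 ± 0.14). Of 25 ribosome biogenesis genes, 14 rose (median 1.04), such as the RNA polymerase I subunit gene Polr1b (1.70 ± 0.13). The tests gave adjusted p = 4.26e-09, 5.11e-06, 1.32e-06 and 2.97e-06 in this order, and adjusted p = 0.156, 0.145, 0.145 and 0.145 with an estimated correlation. Of 9 maternally expressed imprinted genes, 6 rose (median 1.32), such as Grb10 (5.67 ± 0.19) and Phlda2 (5.32 ± 0.22). Of 13 glycolysis genes, 6 rose and 1 fell (median 0.61), with the glucose transporter gene Slc2a3 up by 5.77 ± 0.17. Of 12 trophectoderm genes, 4 rose, with Tfap2c up by 4.79 ± 0.25, and of 4 two-cell-like genes 3 rose, with Usp17la up by 4.19 ± 0.17. These 4 lists passed with adjusted p = 0.00407, 0.0132, 0.0233 and 0.0105, but had adjusted p = 0.268, 0.457, 0.208 and 0.214 with an estimated correlation. Without the genes of the shifted chromosomes, an alternative chosen after the data had been seen, the glycolysis list had adjusted p = 0.227 (range over its alternatives 0.00666 to 0.457) and the two-cell-like list adjusted p = 0.1 (0.00556 to 0.214). The chromosomes left out include 6 and 13, which were shifted in 4F but not in 2F iPS cells against ESC.

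Feeder fibroblast genes were also higher in 2F iPS cells than in NSC, where no feeder cells are stated: 19 of 22 rose and 1 fell, with Col3a1 up by 5.04 ± 0.25 and Fn1 by 3.51 ± 0.17 (median 2.52, adjusted p = 1.03e-07; adjusted p = 0.208 with an estimated correlation). The level of 20 of these 22 genes was above the median of all values in ESC, and that of 10 in NSC. Of the lists that did not pass, mesenchymal genes had 4 members higher and 7 lower, among the latter Zeb1 (−4.80 ± 0.14). The LIF and BMP targets had 8 higher and 2 lower, primed epiblast genes 5 and 2, p53 targets 5 and 0, interferon genes 4 and 3, G1 regulators 4 and 5, and paternally expressed imprinted genes 5 and 6. Immediate early genes had 4 higher and 3 lower, sex-linked genes 3 and 1, neurons 4 and 1, and primitive endoderm 3 and 1. Microglia and endothelium each had 2 higher and 0 lower, and oligodendrocytes and the S and G2/M cell cycle each had 1 higher and 1 lower, with 18 cell cycle genes measured. Of 6 housekeeping genes 1 was higher. The LIF and BMP targets (adjusted p = 0.174) were called with the median of probe sets (adjusted p = 0.0481, range over its alternatives 0.0481 to 0.491), and mesenchymal genes (adjusted p = 0.133) without the feeder genes, chosen after the data had been seen (adjusted p = 0.0151, range 0.0151 to 0.357). Adjusted over the list alone, the counts of every list in this comparison were the same. The median and the mean differed in sign for paternally expressed imprinted genes (0.04 and −0.71) and the S and G2/M cell cycle (−0.03 and 0.07), and the test pointed down for both.

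The comparisons of 4F iPS cells and of ESC with NSC give the counterpart for 4 factors and the reference for an established pluripotent line. The pluripotency list had 33 of 34 genes higher in each, with medians of 6.14 in 4F iPS cells and 6.37 in ESC. Tdgf1 rose by 9.51 ± 0.14 and 9.32 ± 0.14, and Pou5f1 by 8.72 ± 0.15 and 8.73 ± 0.15. Among the 3 genes furthest up were also Rps4l in 4F iPS cells (8.97 ± 0.16) and Dppa5a in ESC (8.70 ± 0.11). Neural stem cell genes fell, 28 of 37 in each, with medians of −4.09 and −3.78. Fabp7 was at 14.25 in NSC and, under the median of all values, at 3.96 in 4F iPS cells and 4.03 in ESC (differences of −10.29 ± 0.15 and −10.23 ± 0.15), and Gpm6b had −8.20 ± 0.10 and −8.22 ± 0.10. The third furthest down was Map2 in 4F iPS cells (−8.18 ± 0.21) and Ptprz1 in ESC (−7.64 ± 0.15). Sox2 did not pass in either, with 0.28 ± 0.16 (adjusted p = 0.178) and 0.32 ± 0.16 (adjusted p = 0.138). Myc fell in both relative to NSC (−2.26 ± 0.25 and −1.98 ± 0.25). The tests of these 2 lists gave adjusted p = 1.43e-22 and 4.8e-20 for 4F iPS cells, and 4.62e-25 and 1.21e-19 for ESC. With an estimated correlation they gave adjusted p = 0.000424 and 0.0109 in both comparisons. The called probe sets numbered 9182 for 4F iPS cells (3908 higher, 5274 lower) and 8549 for ESC (3656 higher, 4893 lower). Counted by gene, 2370 were higher and 2093 lower in 4F iPS cells, and 2073 higher and 2061 lower in ESC.

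Other lists also passed in these comparisons. In 4F iPS cells, epithelial (12 of 16 higher), DNA methylation and Polycomb (13 of 19), germline (13 of 17) and ribosome biogenesis genes (10 of 25) had adjusted p = 3.02e-06, 1.12e-05, 3.1e-08 and 0.00244, and adjusted p = 0.214, 0.145, 0.145 and 0.253 with an estimated correlation. The germline gene Dazl, which encodes an RNA binding protein of germ cells, rose by 7.70 ± 0.32. Feeder fibroblast (13 of 22 higher, 1 lower), trophectoderm (4 of 12) and p53 target genes (10 of 13) had adjusted p = 0.000226, 0.0172 and 0.0156, and adjusted p = 0.338, 0.192 and 0.145 with an estimated correlation. In ESC, epithelial (15 higher), DNA methylation and Polycomb (13), germline (10) and ribosome biogenesis genes (6) had adjusted p = 2.53e-10, 3.02e-06, 2.43e-05 and 0.000504, and adjusted p = 0.145, 0.145, 0.192 and 0.212 with an estimated correlation. Maternally expressed imprinted (8 of 9 higher), trophectoderm (5 of 12), glycolysis (6 of 13) and feeder fibroblast genes (13 higher, 1 lower) had adjusted p = 9.68e-05, 0.00353, 0.00357 and 0.000141, and adjusted p = 0.192, 0.145, 0.421 and 0.326 with an estimated correlation. The glycolysis list of ESC had adjusted p = 0.133 without the genes of the chromosomes that were shifted in iPS cells (range over its alternatives 0.00149 to 0.421). Some lists that did not pass were called under several alternatives. These were maternally expressed imprinted (adjusted p = 0.0521, range over its alternatives 0.0397 to 0.421) and mesenchymal genes (0.0503, range 0.00316 to 0.255) in 4F iPS cells, and mesenchymal genes (0.0521, range 0.00433 to 0.256) and LIF and BMP targets (0.0521, range 0.0372 to 0.38) in ESC. Primitive endoderm genes in 4F iPS cells (adjusted p = 0.125) were called with the median of probe sets alone (0.029, range 0.029 to 0.257). Adjusted over the list alone, the counts were the same, except that LIF and BMP targets in ESC had 9 rather than 8 genes higher. Median and mean differed in sign for paternally expressed imprinted genes (0.30 and −0.61), sex-linked genes (0.54 and −0.07) and the S and G2/M cell cycle (−0.09 and 0.02) in ESC, and the test pointed down for housekeeping genes in 4F iPS cells while their median was 0.12.

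Paternally expressed imprinted and sex-linked genes passed in 4F iPS cells against NSC close to the threshold. Of 16 paternally expressed genes, 1 rose and 5 fell (median −0.36, adjusted p = 0.0489; adjusted p = 0.192 with an estimated correlation). The call ended without 4F replicate 2 (adjusted p = 0.0603), 4F replicate 3 (0.0509) or ESC replicate 3 (0.0521). It also ended with dim probe sets left out (0.132), quantile normalization repeated (0.0513), array medians subtracted (0.0501) or the median of probe sets (0.0886), and the median was 0.29 (adjusted p = 0.663) without the shifted chromosomes. Over all its alternatives adjusted p ranged from 0.0353 to 0.663. Of 5 sex-linked genes, 3 rose (median 1.31, adjusted p = 0.0467; adjusted p = 0.325 with an estimated correlation). That call ended without 4F replicate 1 (0.0614), 4F replicate 3 (0.0518), dim probe sets (0.101) or with the median of probe sets (0.227), over a range of 0.036 to 0.325.

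Most of what separated ESC from NSC also separated iPS cells from NSC. Of 8549 probe sets called between ESC and NSC, 6995 (81.8%) were called the same way in 2F iPS cells and 7 the opposite way. In 4F iPS cells 6802 (79.6%) were called the same way and 9 the opposite way. Independent lists of these sizes would share 863 and 890, and simulated groups that differed from NSC by noise alone shared 0 and 0.05 on average. Across probe sets, which are not independent replicates, the log2 differences from NSC of ESC and 2F iPS cells had r = 0.937, and those of ESC and 4F iPS cells r = 0.914. The shared NSC arrays alone gave a simulated r of 0.601 and 0.600, so the covariances are also given. These were 1.16 and 1.15, against 0.0166 simulated for each.

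The comparison of 2F iPS cells with ESC asks what still separates cells made with Oct4 and Klf4 from ESC. A small set of genes listed for the two-cell-like state was higher in 2F iPS cells. Other genes of that list, Zscan4c, Zscan4d, Zscan4f, Tmem92 and Gm4340, had no probe set assigned to them alone and were not assessed. Of 4 measured members 3 rose, namely Usp17la, a deubiquitinase gene (4.06 ± 0.16, n = 3 and 3), Tcstv1 (3.16 ± 0.14) and Tcstv3 (1.10 ± 0.14), while Zfp352 differed by 0.58 ± 0.14 (adjusted p = 0.0157). In ESC, Usp17la, Tcstv1 and Tcstv3 stood at 4.15, 3.16 and 3.17, under the median of all values, as did Tcstv3 at 4.27 in 2F iPS cells, and Tcstv1 and Tcstv3 had about the same levels in NSC (3.14 and 3.21). The list test gave adjusted p = 4.44e-07, and adjusted p = 0.0938 with an estimated correlation. Feeder fibroblast genes were higher as well. Of 22 members 10 rose and none fell (median 0.97), such as the collagen genes Col3a1 (2.14 ± 0.22), Col1a1 (1.77 ± 0.39) and Col5a2 (1.58 ± 0.23), with adjusted p = 4.85e-11, and adjusted p = 0.145 with an estimated correlation. Mesenchymal genes had 3 of 12 members higher (median 0.61), such as Cd44 (1.36 ± 0.23), with adjusted p = 0.00407, and adjusted p = 0.15 with an estimated correlation. Fn1, Snai2 and Twist1 belong to both of these lists. In all, 1351 probe sets were called (572 higher, 779 lower), 3.00% of those tested, which stood for 704 genes (276 higher, 428 lower), and 37 probe sets differed by more than 8-fold.

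The pluripotency network did not pass as a list between 2F iPS cells and ESC, with 3 members higher, 5 lower and adjusted p = 0.104. It was called, downwards, with quantile normalization repeated (adjusted p = 0.041, range over its alternatives 0.041 to 0.381). Pou5f1 (0.19 ± 0.14, adjusted p = 0.51), Sox2 (−0.32 ± 0.14, adjusted p = 0.187), Klf4 (−0.67 ± 0.19) and Nanog (−0.71 ± 0.18) were not called, the last pair with adjusted p = 0.0373 and 0.02 but under 2-fold. Myc rose by 1.15 ± 0.22 (adjusted p = 0.00414). Zfp42 rose by 1.34 ± 0.17, whereas Prdm14 (−1.34 ± 0.15) and the hormone gene Trh (−1.40 ± 0.20), which lies on chromosome 6, fell. The test of the factor list gave adjusted p = 0.976, and that of their relatives, 2 of which rose, 0.503.

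Among the genes furthest up against ESC were Ccnb1ip1, a gene of meiotic crossing over (3.80 ± 0.23), H2-Q10 of the histocompatibility complex (3.65 ± 0.13), the POU factor gene Pou3f1 (3.64 ± 0.46), the neurofilament gene Nefh (2.90 ± 0.16), Uba1y of the Y chromosome (2.82 ± 0.17) and Wt1 (2.77 ± 0.19). Dnmt3a rose by 2.75 ± 0.21, in 3 of its 5 probe sets, and the zinc finger gene Mecom by 2.61 ± 0.21, in 1 of 3. Furthest down were Rpgrip1 (−5.18 ± 0.13), Trpm1 (−5.14 ± 0.24), Dner (−4.13 ± 0.27), S100a13 (−3.65 ± 0.14), Ubd (−3.63 ± 0.21), Ipp (−3.55 ± 0.14), Fxyd6 (−3.48 ± 0.20), Klf12 (−3.35 ± 0.17), Id4 (−3.17 ± 0.14) and the laminin gene Lama1 (−3.16 ± 0.21). With the median of the probe sets of a gene, 4 of these were no longer called, namely Rpgrip1 (−0.35), Trpm1 (−0.48), Dnmt3a (0.90) and Mecom (0.44). Ccnb1ip1, Rpgrip1 and Klf12 lie on chromosome 14 and Id4 on chromosome 13.

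Germline and trophectoderm genes also differed between 2F iPS cells and ESC. Of 17 germline genes 3 rose, namely Tex19.1 (1.92 ± 0.25), the sperm nucleotide carrier gene Slc25a31 (1.88 ± 0.22) and Mael (1.41 ± 0.13), with adjusted p = 0.000296, and adjusted p = 0.214 with an estimated correlation. Of 12 trophectoderm genes 3 fell, namely Tfap2c (−2.62 ± 0.22), Rhox6 (−2.26 ± 0.12) and Tead4 (−1.30 ± 0.12), with adjusted p = 0.0151, and adjusted p = 0.192 with an estimated correlation. Without the genes of the shifted chromosomes, Tead4 on chromosome 6 among them, the trophectoderm list had adjusted p = 0.0768 (range over its alternatives 0.00795 to 0.192). Chromosome 6 was shifted in 4F iPS cells, with a median of −0.006 in 2F iPS cells against ESC. The loss of the call therefore does not tie the list to a chromosome shift in 2F iPS cells. Of 9 maternally expressed imprinted genes, the noncoding RNA genes Rian (−2.57 ± 0.14), Mirg (−1.85 ± 0.32) and Meg3 (−2.44 ± 0.24) fell and the CDK inhibitor gene Cdkn1c rose (2.01 ± 0.20). With the median of its probe sets Meg3 was not called (−0.53), and the list as a whole did not pass (adjusted p = 0.0862), except without ESC replicate 3 (adjusted p = 0.0473, range over its alternatives 0.0473 to 0.453). Paternally expressed genes had 1 member higher and 2 lower.

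Ribosome biogenesis genes were slightly higher together, 22 of 25 in sign and none past 2-fold (median 0.36), with adjusted p = 6.4e-06, and adjusted p = 0.145 with an estimated correlation. Nop16, which lies on chromosome 13, had the largest difference among them (0.78 ± 0.16). Of 5 sex-linked genes 2 rose. Xist, the RNA of X inactivation, was at 9.37 ± 0.10 in 2F iPS cells and 6.99 ± 0.19 in ESC (2.37 ± 0.13), and its antisense RNA gene Tsix differed by 1.43 ± 0.11. The Y-linked genes Kdm5d, Eif2s3y and Uty stood at 3.70, 10.09 and 7.63 in 2F iPS cells and at 4.18, 9.53 and 7.59 in ESC. The median difference of expressed genes of the X chromosome was 0.03. The sex-linked list had adjusted p = 0.0248, and adjusted p = 0.268 with an estimated correlation. Its call ended without ESC replicate 3 (adjusted p = 0.0761), with dim probe sets left out (0.263) and with the median of probe sets (0.0669), under which Xist (0.57) was not called. Over its alternatives adjusted p ranged from 0.00979 to 0.268. Neural stem cell genes had 3 of 37 members higher and 1 lower, with the eye and brain factor gene Pax6 up by 2.29 ± 0.16, a median of 0.11 and adjusted p = 0.049; adjusted p = 0.357 with an estimated correlation. That call ended without NSC replicate 3 (0.0501), 2F replicate 1 (0.0614), 2F replicate 2 (median 0.06, adjusted p = 0.0784), 4F replicate 2 (0.0614) or ESC replicate 1 (0.0569), over a range of 0.0265 to 0.357.

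Of the lists that did not pass between 2F iPS cells and ESC, epithelial genes had 3 members lower, such as Cldn4 (−1.45 ± 0.25), and none higher (adjusted p = 0.0559). They were called, downwards, with the median of probe sets (adjusted p = 0.0246) and without NSC replicate 2 (0.0429), NSC replicate 3 (0.0413) or ESC replicate 2 (0.0279), over a range of 0.0246 to 0.51. Glycolysis genes (adjusted p = 0.0622) were called, downwards, with quantile normalization repeated (0.0332), the median of probe sets (0.0385) and without 2F replicate 1 (0.0262) or ESC replicate 2 (0.0279), over a range of 0.0262 to 0.557. Primed epiblast genes had 2 higher, Otx2 (2.17 ± 0.36) on chromosome 14 and Pou3f1, and 1 lower, Lefty2 (−2.83 ± 0.26). Immediate early genes had 1 higher and 2 lower, with Fos at −2.09 ± 0.33. Adjusted over the list alone the counts were the same, except for DNA methylation and Polycomb genes (2 rather than 1 higher) and immediate early genes (2 rather than 1 higher). Median and mean differed in sign for reprogramming factors (−0.07 and 0.09), microglia (0.09 and −0.16), paternally expressed imprinted genes (0.03 and −0.10), interferon genes (−0.03 and 0.09) and immediate early genes (0.06 and −0.06). The test pointed up for these lists, except down for the imprinted genes.

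The comparison of 4F iPS cells with ESC is the counterpart for 4 factors. Germline genes were higher in 4F iPS cells and epithelial and imprinted genes lower. Of 17 germline genes 10 rose and 1 fell (median 1.79), among them Dazl (4.60 ± 0.29, n = 3 and 3), Asz1 (3.81 ± 0.13), Slc25a31 (3.61 ± 0.22) and the meiotic chromosome axis gene Hormad1 (3.50 ± 0.14). Of 16 epithelial genes 8 fell and none rose (median −0.97), among them the desmosome gene Dsp (−3.86 ± 0.20) and the claudin genes Cldn7 (−3.04 ± 0.20), Cldn4 (−2.98 ± 0.25) and Cldn6 (−2.39 ± 0.22). Of maternally expressed imprinted genes 4 of 9 fell (median −0.96), with Rian at −3.36 ± 0.14 and Mirg at −2.06 ± 0.32, and of paternally expressed ones 5 of 16 (median −0.56), with Nnat at −1.41 ± 0.23. In the order germline, epithelial, maternal and paternal, the lists had adjusted p = 2.1e-09, 2.28e-11, 5.17e-06 and 0.0011, and adjusted p = 0.141, 0.145, 0.145 and 0.116 with an estimated correlation. Asz1 lies on chromosome 6 and Dsp on chromosome 13, and the actin 3′ minus 5′ difference was higher in 4F iPS cells (0.55) than in ESC (0.27), while that of Gapdh was −0.04 and −0.07. In all, 1956 probe sets were called (821 higher, 1135 lower), 4.34% of those tested, which stood for 981 genes (507 higher, 474 lower).

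The genes furthest up in 4F iPS cells were Stra8, induced by retinoic acid at the entry to meiosis (5.43 ± 0.16), which lies on chromosome 6, the Polycomb-related gene Scml2 (4.69 ± 0.10) and Dazl. Those furthest down were Dsp, Id4 (−3.51 ± 0.14) and Serpinb6c (−3.50 ± 0.18), which lie on chromosome 13. None of the 4 factor genes was called, with Pou5f1 at −0.00 ± 0.14 (adjusted p = 0.988), Sox2 at −0.04 ± 0.14 (0.892), Klf4 at 0.53 ± 0.19 (0.0759) and Myc at −0.28 ± 0.22 (0.443). The factor list had adjusted p = 0.969, and the pluripotency network, with 1 gene higher and 2 lower, adjusted p = 0.729. Feeder fibroblast genes had a median of 0.34, none called, and adjusted p = 0.332.

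Glycolysis genes were lower together in 4F iPS cells than in ESC, 12 of 13 in sign with 1 past 2-fold (median −0.40), with adjusted p = 0.00244, and adjusted p = 0.418 with an estimated correlation. The Y-linked gene Kdm5d was at 8.38 ± 0.04 in 4F iPS cells and 4.18 ± 0.13 in ESC (4.20 ± 0.14). Of 5 sex-linked genes 3 rose, with adjusted p = 0.0232, and adjusted p = 0.268 with an estimated correlation, a call that ended without 4F replicate 1 (adjusted p = 0.0614, range over its alternatives 0.0112 to 0.268). Of 13 p53 targets, the cyclin gene Ccng1 (1.45 ± 0.10) and the CDK inhibitor gene Cdkn1a (1.17 ± 0.14) rose and Perp fell (−1.24 ± 0.12). With the median of its probe sets Cdkn1a was not called (0.97). Another CDK inhibitor gene, Cdkn2a, rose by 1.84 ± 0.15. The p53 list had 2 members higher and 1 lower and adjusted p = 0.0472, and adjusted p = 0.192 with an estimated correlation. Its call ended without 4F replicate 1 (median 0.14, adjusted p = 0.0821), 4F replicate 2 (median 0.48, adjusted p = 0.0564) or ESC replicate 1 (0.0655), with dim probe sets left out (0.066), with the median of probe sets (0.0876) and without the shifted chromosomes (0.0529). Over its alternatives adjusted p ranged from 0.0248 to 0.192.

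The S and G2/M cell cycle list also passed in 4F iPS cells against ESC, with 15 of 18 genes higher in sign and none past 2-fold (median 0.26, adjusted p = 0.0489; adjusted p = 0.378 with an estimated correlation). The replication gene Mcm6 differed by 0.66 ± 0.11. This call ended without 2F replicate 1 (0.0546), 2F replicate 2 (0.0521), 2F replicate 3 (0.0517), 4F replicate 2 (0.0915), 4F replicate 3 (0.069), ESC replicate 1 (0.104) or ESC replicate 3 (0.069). It also ended with a replicate block, with dim probe sets left out (0.0713), array medians subtracted (0.0501), the median of probe sets (0.353) and without the shifted chromosomes (0.0978), and adjusted p ranged from 0.015 to 0.378 over its alternatives. Adjusted over the list alone the counts in this comparison were the same, except for immediate early genes (2 rather than 1 higher). Median and mean differed in sign for reprogramming factors (−0.02 and 0.05), their relatives (0.19 and −0.06), neural stem cell genes (0.03 and −0.04), neurons (0.07 and −0.34) and G1 regulators (−0.04 and 0.17), and the test pointed up for the last and down for the others.

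**Figure D2:**
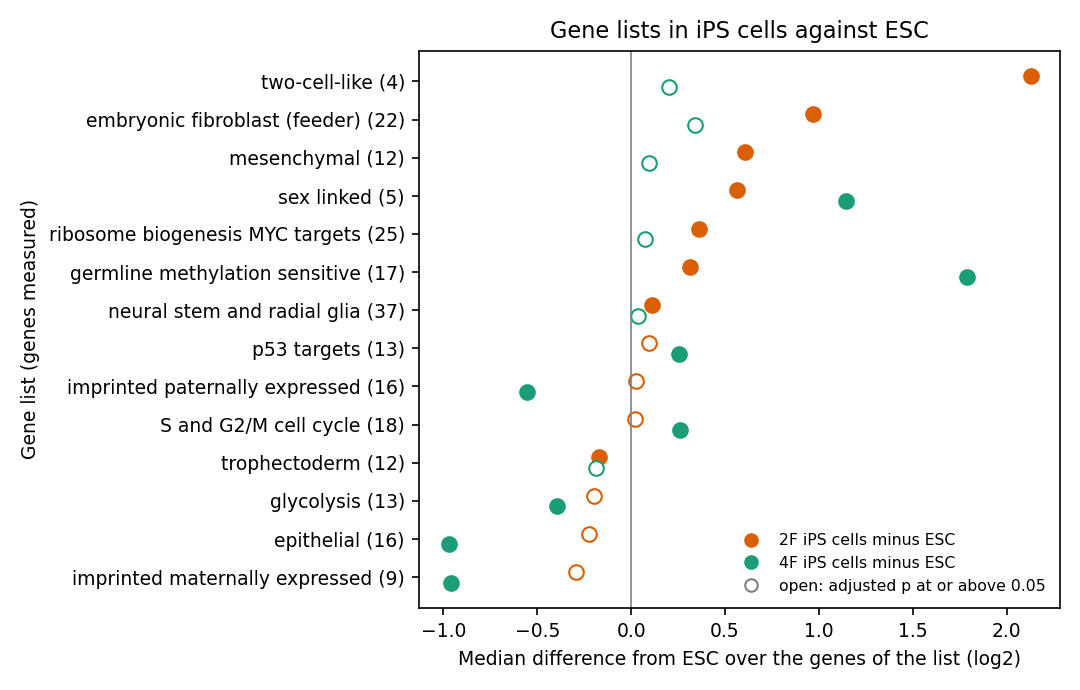
Median log2 difference from ESC (x axis, log2 units) of 14 gene lists in 2F and 4F iPS cells (n = 3 each), with the number of measured genes in parentheses. Filled points had an adjusted p under 0.05 and open points did not; epithelial genes lie at −0.97 in 4F iPS cells and feeder fibroblast genes at 0.97 in 2F iPS cells.

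The comparison of 2F with 4F iPS cells asks how the number of factors goes with expression in cells made from NSC of a mixed background. The labels give neither the number of colonies behind each kind nor any batch. Differences between single colonies, between donors or between array runs are therefore not separated from the number of factors. Epithelial, two-cell-like and feeder fibroblast genes were higher in 2F iPS cells, and germline genes lower. Epithelial genes had 8 of 16 members higher (median 1.12), such as Dsp (2.42 ± 0.20, n = 3 and 3), the keratin gene Krt8 (2.31 ± 0.14) and Cldn7 (1.81 ± 0.20). Two-cell-like genes had 3 of 4 higher, with Usp17la at 3.36 ± 0.16 and Tcstv1, which lies on chromosome 13, at 3.02 ± 0.14. Feeder fibroblast genes had 6 of 22 higher, such as Col6a1 (2.13 ± 0.29). Germline genes had 8 of 17 lower, such as Dazl (−3.97 ± 0.29) and Asz1 (−3.57 ± 0.13). In this order the lists had adjusted p = 4.8e-07, 2.72e-05, 1.24e-06 and 3.78e-05, and adjusted p = 0.207, 0.145, 0.225 and 0.192 with an estimated correlation. The actin 3′ minus 5′ difference was lower in 2F (0.22) than in 4F iPS cells (0.55), while that of Gapdh was −0.09 and −0.04. In all, 2480 probe sets were called (1328 higher in 2F iPS cells, 1152 lower), 5.51% of those tested, which stood for 1223 genes, 513 higher and 710 lower.

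Furthest up in 2F iPS cells were the neurofilament gene Nefl (3.95 ± 0.15), Gadd45g (3.53 ± 0.25), Usp17la, H2-Q10 (3.27 ± 0.13), Tcstv1, Mecom (2.92 ± 0.21), the neuroendocrine factor gene Insm1 (2.81 ± 0.12), Cdkn1c (2.78 ± 0.20), the carbonic anhydrase gene Car3 (2.68 ± 0.27) and Tmem54 (2.60 ± 0.27). Furthest down were Rpgrip1 (−5.72 ± 0.13), Stra8 (−5.10 ± 0.16), Kdm5d (−4.68 ± 0.14), Scml2 (−4.57 ± 0.10), Ipp (−4.18 ± 0.14), Efhc2 (−4.12 ± 0.17), Nxf3 (−4.01 ± 0.24), Rhox13 (−3.98 ± 0.20), Dazl and Pnma5 (−3.85 ± 0.23). With the median of their probe sets Rpgrip1 (−0.78), Mecom (0.71) and Car3 (0.92) were not called. Nefl lies on chromosome 14 and Gadd45g on chromosome 13.

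Among the factor genes, Klf4 was lower in 2F than in 4F iPS cells (−1.20 ± 0.19) and Myc higher (1.44 ± 0.22), and Pou5f1 (0.19 ± 0.14, adjusted p = 0.369) and Sox2 (−0.28 ± 0.14, adjusted p = 0.191) were not called. Klf4 was not called with the median of its probe sets (−0.90). Nanog was lower (−1.06 ± 0.18) and was not called without 2F replicate 1 (−0.93) or 4F replicate 3 (−0.88). The pluripotency network had 2 genes higher, with Zfp42 at 1.76 ± 0.17, and 8 lower, with Prdm14 at −1.71 ± 0.15 (adjusted p = 0.41). Xist was higher in 2F iPS cells by 2.57 ± 0.13, and not called with the median of its probe sets (0.50).

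Imprinted, ribosome biogenesis and neural stem cell lists also passed between 2F and 4F iPS cells. Of paternally expressed genes 5 of 16 were higher, such as Nnat (1.33 ± 0.23), and 1 lower (median 0.50), and of maternally expressed ones 3 of 9 were higher, such as Phlda2 (1.30 ± 0.20; median 0.55). Of ribosome biogenesis genes 1 of 25 was higher (median 0.25). Of neural stem cell genes 6 of 37 were higher, such as Cdh2 (1.96 ± 0.16) and Olig2 (1.72 ± 0.18), with a median of 0.08. In this order the lists had adjusted p = 0.0105, 0.00433, 0.00129 and 0.0178, and adjusted p = 0.145, 0.268, 0.225 and 0.275 with an estimated correlation. The maternal list was not called with the median of probe sets (0.39, adjusted p = 0.0535, range over its alternatives 0.000818 to 0.268). Of the lists that did not pass, interferon genes (adjusted p = 0.0559) were called, upwards, with dim probe sets left out (0.0208) and without 2F replicate 1 (0.0469) or 4F replicate 1 (0.0169), over a range of 0.0169 to 0.338. Neurons (adjusted p = 0.0634) were called without 2F replicate 1 (0.0483) or 4F replicate 1 (0.0409), over 0.0409 to 0.292. Glycolysis genes (adjusted p = 0.288) were called without 4F replicate 1 (0.0487, range 0.0487 to 0.762), and mesenchymal genes (adjusted p = 0.13) with the median of probe sets (0.0386, range 0.0386 to 0.357). Adjusted over the list alone the counts were the same, except for neurons (2 rather than 1 higher). Median and mean differed in sign for reprogramming factors (−0.04 and 0.04), primitive endoderm (0.02 and −0.16), G1 regulators (−0.24 and 0.02) and housekeeping genes (−0.03 and 0.11). The test pointed up for these, except down for primitive endoderm, and it pointed up for endothelium with a median of −0.01.

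Whole chromosomes or long parts of them differed from ESC together. In 4F iPS cells the expressed genes of chromosome 13 had a median difference of −0.60 and those of chromosome 6 of 0.30. Chromosome 13, with 3.54% of the expressed genes, held 19.5% of the genes called lower, and chromosome 6, with 4.95% of them, held 15.7% of those called higher. In 2F iPS cells chromosome 14 had a median of −0.37. Its shifted blocks, 10 of 15 and all side by side, held 73 genes called lower and 3 called higher, 18.5% of all genes called lower against 2.23% of expressed genes, whereas the other 5 blocks held 7 higher and 5 lower. Relative to ESC, the median of these 10 blocks was −0.67 ± 0.02 (SD) in 2F iPS cells, −0.32 ± 0.01 in 4F iPS cells and −0.22 ± 0.01 in NSC, and that of the other 5 was 0.30 ± 0.07 in 2F iPS cells. On chromosome 13 the medians were −0.57 ± 0.04 in 4F iPS cells, −0.04 ± 0.03 in 2F iPS cells and −0.08 ± 0.03 in NSC, and on chromosome 6 they were 0.33 ± 0.04, −0.01 ± 0.01 and −0.12 ± 0.02. Over all expressed genes the median of NSC relative to ESC was −0.12, so part of the NSC values is not particular to these chromosomes. Some further chromosome medians were smaller. In 2F iPS cells chromosome 8 had a median of 0.16, with 26 of 26 blocks above 0. In 4F iPS cells chromosome 3 had 0.19, with blocks from −0.60 to 0.75, chromosome 1 had 0.19, with 22 of 26 blocks above 0, chromosome 14 had −0.15, with 9 of 15 below 0, and chromosome 8 had −0.12, with 24 of 26 below 0. Of the genes named here, Asz1, Nanog, Ptprz1, Rps4l, Slc2a3, Stra8, Tead4 and Trh lie on chromosome 6, Dsp, Gadd45g, Id4, Nop16, Serpinb6c, Tcstv1 and Tcstv3 on chromosome 13, and Ccnb1ip1, Klf5, Klf12, Nefl, Otx2 and Rpgrip1 on chromosome 14. The order of genes is that of the mouse assembly GRCm38.p6.

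**Figure D3:**
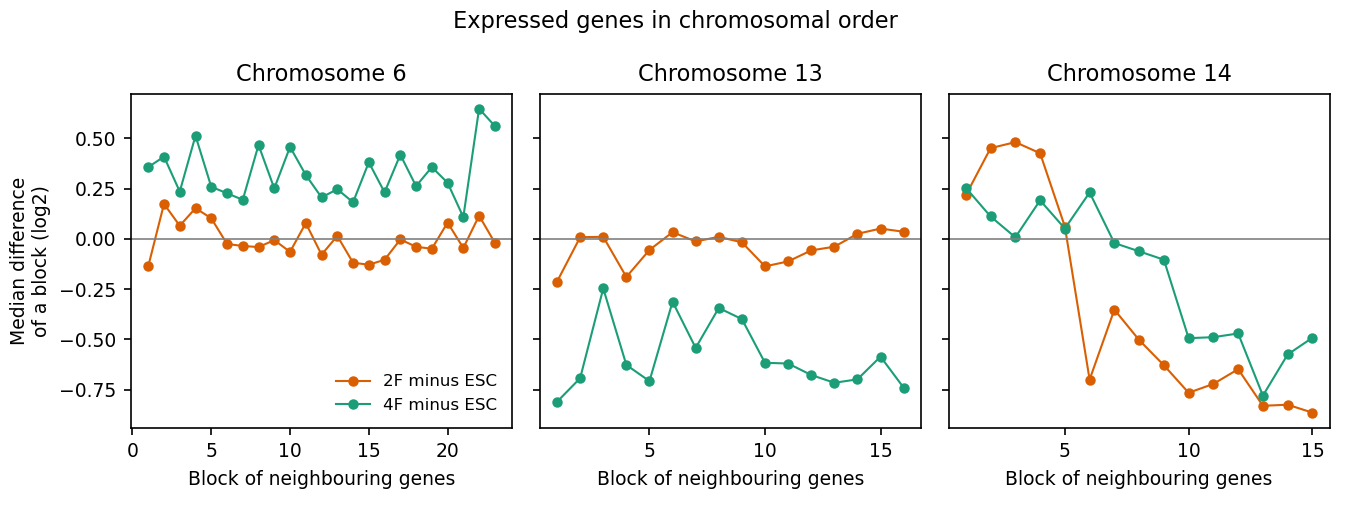
Median log2 difference from ESC (y axis, log2 units) of blocks of 25 neighbouring expressed genes in their order along chromosomes 6, 13 and 14 (x axis, block number), with 1 point per block for 2F and 4F iPS cells. On chromosome 13 all 16 blocks lie below 0 in 4F iPS cells, and on chromosome 14 blocks 6 to 15 lie below 0 in 2F iPS cells.

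Differences from ESC were set against the difference between ESC and NSC. Of 1351 probe sets called in 2F iPS cells against ESC, 820 were also called between ESC and NSC. In 602 of these (73.4%) 2F iPS cells lay on the NSC side of ESC and in 218 on the far side, where independent lists would give 125 and 131. Examples on the NSC side are Trpm1, Ubd, Id4, Lama1 and Tfap2c, which were lower than in ESC. In 4F iPS cells 1036 were also called between ESC and NSC, 747 (72.1%) on the NSC side and 289 on the far side, against 181 and 190, with Kdm5d, Dsp and Rian as examples on the NSC side. Simulated groups that differed from ESC by noise alone gave at most 0.05 on average. Both contrasts use the ESC arrays, so a deviation of those arrays alone would also fall on the NSC side. Independent lists and this simulation do not allow for that. The background of the cells goes with the contrast of ESC and NSC, since NSC and iPS cells come from a mixed background that ESC do not share. For some genes 2F or 4F iPS cells alone lay on the NSC side by a called difference. Kdm5d stood at 7.71 in NSC, 8.38 in 4F iPS cells, 3.70 in 2F iPS cells and 4.18 in ESC, whereas Ipp stood at 7.06, 10.08, 5.90 and 9.45 in this order. Kdm5d in 2F iPS cells and in ESC lay under the median of all values. Ipp differed by less than 2-fold between 4F iPS cells and ESC. Such single genes do not decide whether background is the cause.

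Both kinds of iPS cells differed from ESC in part in the same way. The comparisons with ESC shared 403 probe sets called the same way, 107 higher and 296 lower, against 30.1 for independent lists and 0 in simulated data. Another 25 were called the opposite way, for which the overlap of independent lists was not computed. Among the named genes Id4, Rian, Dner and S100a13 were lower and Nefh, Uba1y and Ccnb1ip1 higher in both. The differences had r = 0.353 across probe sets, which are not independent replicates, where the shared ESC arrays alone gave 0.5. The covariance was 0.0644, against 0.0110 in simulated data. Whole arrays of 2F iPS cells correlated with those of ESC at a mean r of 0.983 ± 0.000391 (SD, n = 3) and those of 4F iPS cells at 0.976 ± 0.00154, a difference of 0.00722, or 0.0147 with dim probe sets left out. A two-sided exact permutation test gave p = 0.1, the smallest that 20 splits allow. Arrays of NSC correlated with those of ESC at 0.892, of 2F iPS cells at 0.893 and of 4F iPS cells at 0.887.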

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

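The tests of the noise of shared ESC arrays, of matched random gene sets, of the share of genes shifted per chromosome, of a background shared along the shifted chromosomes and of the side on which NSC lie were chosen only after the result was seen, as was leaving out the shifted chromosomes. The tests on splits of the arrays, on blocks of neighbouring genes, on a second fibroblast list and on other probe sets of the same genes were set beforehand.

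The changes in 2F and 4F iPS cells differed when compared directly, with 2480 probe sets called. The list test, which compares the genes of a list with all others, passed for 8 gene lists. The median log2 difference of 2F minus 4F iPS cells was not itself tested. It was 0.0785 for neural stem cell genes, 0.75 for feeder fibroblast genes, 2.08 for two-cell-like genes and −0.64 for germline genes. It was 0.50 for paternally and 0.55 for maternally expressed imprinted genes, 0.25 for ribosome biogenesis and 1.12 for epithelial genes. With an estimated correlation, 0 of 29 lists were called in this comparison, where the smallest adjusted p was 0.145. Gadd45g differed by 3.53 and was called in opposite directions against ESC, at 1.07 in 2F and −2.46 in 4F iPS cells.

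Regrouping the 6 arrays of a comparison gives 10 splits into 3 and 3, too few for a share under 0.05. Every split but the real one mixes arrays of both groups. Any difference between the groups then adds to the spread, so counts near 0 in those splits carry little weight. In limma, 1 of the 10 splits, the real one, reached the 1351 called probe sets of 2F iPS cells against ESC, and the highest of the other splits was 0 (2001 at an unadjusted p under 0.05, against 10501 in the real split). For 4F iPS cells against ESC it was 1 of 10 as well, with 1956 called and 0 in the highest other split (3543 against 13975 unadjusted). For 2F against 4F iPS cells it was again 1 of 10, with 2480 called and 0 in the highest other split (2693 against 14982 unadjusted).

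Expressed genes of chromosome 14 in 2F iPS cells and of chromosomes 13 and 6 in 4F iPS cells were shifted together relative to ESC, with medians of −0.37, −0.60 and 0.30. Array-wide differences in RNA quality or scaling that act by expression level are argued against by 10000 random gene sets matched on that level. Their farthest medians were −0.0648, −0.0573 and 0.0979. The sets were matched on nothing else, so effects of RNA quality that act otherwise were not tested. Regulation of a minority of genes is argued against on chromosomes 13 and 6, where 87.1% and 77.1% of genes were shifted the same way, but not on chromosome 14 (67.3%). A background that NSC and both kinds of iPS cells share is argued against on chromosomes 13 and 6, where NSC and 2F iPS cells showed at most 13.2% and −3.54% of the shift. On chromosome 14 it is left open, since 4F iPS cells showed 47.6% of the shift. NSC had −0.22 in these blocks, against −0.12 over all expressed genes. A change in dose of a whole chromosome or long segment predicted every block shifted the same way and beyond the range of unshifted chromosomes. On chromosome 13 100% of the blocks were shifted, 15 of 16 beyond that range. On chromosome 6 100% were shifted, 3 of 23 beyond the range, and on chromosome 14 66.7% were shifted. The prediction was thus not met in full on any of them, and by a wide margin on chromosome 6, so a change in dose is left open. The bound of under 80% of blocks, set beforehand, excludes a whole-chromosome change for chromosome 14 but was wrong for a segment, because the 10 lower blocks form 1 uninterrupted run, though the median of 0.30 in the other 5 blocks is not what a lost segment alone would give; without DNA, dose cannot be told apart from regulation along a chromosome or, on chromosome 14, from a shared background, and a biological difference between the kinds of cells remains untested.

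Feeder fibroblast genes were higher in 2F iPS cells than in ESC, 21 of 22 in sign with 10 called, and their medians were 0.99, 0.98 and 0.77 in the 3 arrays against 0.33, 0.49 and 0.02 in 4F iPS cells. More feeder RNA in the 2F arrays predicted that at least 80% of a second list of fibroblast genes would be higher, and 60% or fewer if not; 76.3% were (29 of 38, with 7 called higher and 1 lower), which leaves it a possible explanation. The 5 brightest genes of these lists in 2F iPS cells differed from ESC by −0.07 (Fn1), −0.67 (Lgals1), 0.05 (Pcolce), 0.54 (Tpm2) and −0.25 (Cnn2), but stood at 9.48 or higher in ESC, a level that would hide a small share of feeder RNA, whereas Col3a1 stood at 9.80 in 2F iPS cells and 7.66 in ESC. Of the first list 20 of 22 genes and of the second 29 of 38 lay above the median of all values in ESC, so the markers are not free of signal from cultures grown on the same kind of feeder. Feeder RNA cannot be told apart from expression by the iPS cells themselves, since no sort that would remove feeders is stated beyond the picking of colonies, and a biological effect of the number of factors remains untested.

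The comparisons of 2F and 4F iPS cells with ESC shared 403 probe sets called the same way, 107 higher and 296 lower. Simulated unchanged groups with independent noise shared 0. Such groups hold almost no calls, so this count could hardly have been higher. It cannot show how much noise of the shared ESC arrays adds to an overlap of real calls. The simulation held no deviation common to the ESC arrays, so it cannot judge one. Sequence differences between the mouse backgrounds that change single probe sets are argued against as the whole cause, because 89.6% of other bright probe sets of the same genes (173 of 193) moved the same way in both, above the 80% set beforehand. A background or origin that NSC and both kinds of iPS cells share is a possible explanation, with NSC on the iPS side of ESC for 73.0% of the probe sets (294 of 403), between the 60% that would exclude it and the 80% it predicted. It cannot be told apart from a difference between iPS cells and ESC as kinds of cells, because in these samples all ESC have one background and all other cells another, mixed one. For some genes outside this set, 4F iPS cells alone (Kdm5d) or 2F iPS cells alone (Ipp) lay on the NSC side by a called difference. That does not decide between these explanations.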

How the results depend on the processing

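Leaving out the shifted chromosomes or the feeder list was chosen after the data had been seen. Under an adjusted p of 0.01, dim or cross-hybridising probe sets left out, repeated quantile normalization, subtracted medians, array weights, another prior and only 2 groups, every count of called probe sets stayed within 1.5 times its value. With no fold minimum the counts grew, by construction, to 18962 (2F against NSC), 20440 (4F against NSC), 18031 (ESC against NSC), 5919 (2F against ESC), 9049 (4F against ESC) and 10355 (2F against 4F), with 2658 and 3638 of 2F and 4F iPS cells on the NSC side and 2219 common to both. Counting 1 probe set per gene tested fewer features and gave 4384, 4464, 4137, 706, 983 and 1226 in this order, with 320, 395 and 219. The median of the probe sets of each gene gave 3884, 3969, 3785, 565, 790 and 967, with 267, 327 and 173. The share of called features that were higher in 4F iPS cells against NSC rose from 42.6% to 52.6% with no fold minimum and 53.1% with 1 probe set per gene, and for 2F against 4F it went from 53.5% to 42.0% with 1 probe set per gene. The difference in array correlation was 0.0147 with dim probe sets left out. Without the shifted chromosomes 1082 probe sets were called for 2F against ESC, 1530 for 4F against ESC and 1993 for 2F against 4F.

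Without each array in turn the counts ran from 8845 to 9009 for 2F against NSC, 9077 to 9449 for 4F against NSC, 8535 to 8660 for ESC against NSC, 1330 to 1384 for 2F against ESC, 1865 to 2311 for 4F against ESC and 2441 to 2648 for 2F against 4F. Those on the NSC side ran from 569 to 639 (2F) and 701 to 862 (4F), the common ones from 375 to 444, the shares from 81.0% to 82.0% (2F) and 78.1% to 80.4% (4F), and the correlation difference from 0.00654 to 0.00805. Where 1 NSC array was left, it was assumed to vary like the other groups.

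Of 854 values of named genes, 541 of them called, 79 lost their call with the sign kept and 10 gained one with the median of probe sets. In the fits without each array 9221 of 9394 values kept theirs. With the median of probe sets 2 further genes lost their call and changed sign, Bub1 in 4F against NSC to −0.25 (adjusted p = 0.167) and Tfcp2l1 in 2F against ESC to 0.0165 (adjusted p = 0.97), and the cause was not tested. Of 56 called list results 50 lost their call with an estimated correlation, 7 without the shifted chromosomes, 6 with the median of probe sets and 5 without dim probe sets. Without the feeder genes, none lost and 3 gained a call, the mesenchymal list against NSC in 2F (−1.78), 4F (−1.99) and ESC (−2.26).

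A replicate block gave 8905, 9185, 8542, 1348, 1953 and 2478 called probe sets. Of the list results 1 lost its call under it, the S and G2/M cell cycle in 4F iPS cells against ESC (adjusted p = 0.0534), and 6 gained one. These were epithelial genes in 2F against ESC (adjusted p = 0.0343), interferon genes in 2F against 4F (0.0477), maternally expressed imprinted (0.0461) and mesenchymal genes (0.0461) in 4F against NSC, and mesenchymal genes (0.0467) and LIF and BMP targets (0.0467) in ESC against NSC. Of the named gene values Bub1 in 4F against NSC (0.98) and Igf2r in ESC against NSC (0.98) lost and Hspa1b in 2F against ESC (1.20) gained a call. The label numbers gave no sign of pairing: 3 of 15 pairs of arrays with the same number correlated above 0.1 after group means were removed (median −0.155), and 1 array correlated best with its own number. With so few arrays per group these deviations are bound to each other, so pairing is not excluded. Dim signals limit what the arrays can show. Of simulated 1.5-fold changes 44.8% passed the adjusted p for 2F against ESC, and 1.49% were called with the fold minimum.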

Other observations

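The genes named in this part were chosen after their values were seen. They differed from ESC in both kinds of iPS cells. Syce1, a component of the synaptonemal complex, was 2.09 higher on the log2 scale in 2F and 3.17 higher in 4F iPS cells (n = 3 each). Sohlh2, a transcription factor gene of early germ cells, was higher by 1.25 and 4.03. Rpl39l, a relative of a ribosomal protein gene, was higher by 2.19 and 2.83, and stood at 4.73 in NSC and 8.08 in ESC. The keratin gene Krt17 was lower in both, at −2.57 and −3.12. The Polycomb gene Bmi1 was at 11.73 in NSC, 5.86 in ESC, 7.27 in 2F and 8.81 in 4F iPS cells, and so lay on the NSC side of ESC in both.

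In 8 genes, each by its representative probe set, the calls against ESC went in opposite directions in 2F and 4F iPS cells. Besides Gadd45g these were Tasor2 (1.23 in 2F and −1.22 in 4F) and Chac1 (1.29 and −1.14), which were higher in 2F iPS cells. The receptor gene Kit (−1.26 and 1.32), the tau gene Mapt (−1.33 and 1.07), Bach2 (−1.59 and 1.16), Bbip1 (−1.08 and 1.33) and Igsf3 (−1.07 and 1.20) were lower in 2F and higher in 4F iPS cells. The direct comparison of 2F with 4F gave differences from −2.76 for Bach2 to 3.53 for Gadd45g. How many such opposite calls independent lists would give was not computed.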
